A study of Mus musculus with 2 samples.

How the data were processed

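RNA from liver of BALB/c mice at 5 months of age was measured by RNA sequencing on an Illumina HiSeq2000, per the labels, with 1 library labelled WT and 1 labelled SRSF2-KO. Total RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols. Bowtie 0.12.2 and the mouse build mm9 are named per the submitters' processing notes. The authors deposited 1 table of FPKM (fragments scaled to transcript length and to the mapped fragments of the library) with 1 value per gene row and library. The program that estimated FPKM, the gene annotation, the strandedness of the libraries and any filters are not given in the sources used here. FPKM from the authors are already scaled for depth and transcript length, and they do not sum to the same total: the deposited values summed to 523254 in the library labelled SRSF2-KO and 666262 in the library labelled WT. Because of this, log2 ratios carry an offset that depends on the scaling, and 3 rescalings were run as alternatives.

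Each column of the table was assigned to a library by its name, KO or WT. The table held 36771 rows, of which 18336 were 0 in both libraries. Gene symbols were used as given. Of these rows, 25 carried calendar dates in place of symbols, as spreadsheet programs make from some gene names, and these were counted but not named (14 of them had at least 1 FPKM). A shared symbol was carried by 2489 rows (274 symbols, 93 rows with at least 1 FPKM). For lists and named genes, the row with the highest mean FPKM stood for a repeated symbol. Of the 11428 rows with at least 1 FPKM in at least 1 library, 90.6% matched a symbol of the GENCODE M21 annotation, which belongs to another build (GRCm38) and was used only for transcript lengths and for which genes are protein-coding. No coordinates are given.

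The measure was log2((KO + 1)/(WT + 1)) of FPKM, with a pseudocount of 1, among rows with at least 1 FPKM in at least 1 library. Rows at least 2-fold apart (log2 ratio of at least 1 or at most -1) were counted. With 1 library per genotype no test was run and no p-value is given. For 37 gene lists fixed before the data were examined, holding 600 symbols of which 598 were in the table (6 under an older name), the median log2 ratio over measured members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression (seed 11). A list was said to stand apart when its median lay below the 2.5 or above the 97.5 percentile. The list with fewer than 3 measured members was given as values only. The named genes followed a rule also fixed before the data were examined: Srsf2, the 12 highest and 12 lowest log2 ratios among symbols with at least 1 FPKM in at least 1 library, in each list the 2 highest and 2 lowest measured members (at least the 2 on the side of the median being printed), and the 5 most abundant rows of each library. The value of 1 list member is not reported here. Other genes are named where they illustrate a list or, where so stated, after their values were seen.

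Depth was estimated from the values. Low FPKM values stepped in whole reads: of 479 genes with low values in both libraries (under 0.05 FPKM in KO and 0.08 in WT), 74.3% had a KO to WT ratio within 0.04 log2 units of 1 of 7 small whole-read ratios, of which the commonest, 0.792, stands for equal reads. Values of genes with a single GENCODE M21 transcript of 1000 to 8000 bases were then fitted with a depth and a length offset, which gave 24400000 fragments for the library labelled SRSF2-KO and 19400000 for the library labelled WT, both with an offset of 180 bases. Of the values worth 1 to 3 reads, 71.9% (467 genes) and 75.1% (434 genes) came within 0.1 reads of a whole number. Estimated reads per gene, from these depths and the median length of protein-coding transcripts, gave 95% exact (Clopper-Pearson) intervals for ratios between the 2 libraries. They cover counting error only, depend on lengths from another annotation, and were not computed for transcripts under 400 bases, where a few reads make a large FPKM.

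The scripts were tested on simulated data drawn from the real values, with depths set near those estimated above. Of 200 genes given a 4-fold difference among 11428, 89% came out at least 2-fold apart (90% without counting error, since the pseudocount of 1 shrinks low genes), and 100% of the 112 with a mean of at least 5 FPKM did. Of 11228 unchanged genes, 0 came out at least 2-fold apart from counting error alone. In these expression simulations every gene had the same transcript length. Short transcripts, where a few reads make a large FPKM, were therefore not covered. Of 200 unchanged lists of 15 genes, 7% lay outside their random lists. Of 50 lists raised 1.5-fold, drawn only from genes with a mean of at least 5 FPKM, 100% lay above their random lists. The spread in these simulated lists came from counting error only, so the rates need not hold for the real lists. The simulated depths were recovered.

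Alternatives fixed before the data were examined were pseudocounts of 0.1 and 3, no filter on low values, a filter of 5 FPKM, KO values rescaled to a median log2 ratio of 0 (over the 10198 rows with at least 1 FPKM in both libraries), equal sums without the 50 rows of highest mean FPKM, both libraries rescaled to the same total (TPM), summed rows of 1 symbol, random lists not matched on expression, a 4-fold threshold, a counting interval for each fold and the 50 most abundant rows. A subset of protein-coding genes, lists restricted to members present in both libraries and 13 gene families were added after the values were seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.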

Results

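Liver RNA was sequenced from mice at 5 months of age, as 1 library labelled wild type (WT) and 1 labelled SRSF2-KO, from a mouse in which Srsf2 was deleted in the liver according to the study's design text. Srsf2 codes for an SR protein, a family of RNA-binding factors that direct the choice of splice sites. The comparison addresses how the liver transcriptome differed between the 2 genotypes. There were no replicates, so no difference below has a replicate check and none was tested. The deposited table held 36771 rows, of which 17648 were above 0 in the library labelled SRSF2-KO and 16635 in the library labelled WT. Steps of whole reads in the low values gave an estimated depth of 24400000 and 19400000 fragments, respectively.

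Srsf2 itself was not lower in the library labelled SRSF2-KO. Its level was 45.3 FPKM there and 38.2 FPKM in the library labelled WT, a ratio of 1.19 with a 95% exact (Clopper-Pearson) interval of 1.10 to 1.29 that covers counting error only. The targeted gene thus went against its label, and every direction given below is one between a library labelled SRSF2-KO and a library labelled WT. The table gives 1 value per gene and does not say which part of Srsf2 was deleted. The other SR protein genes lay close by, from a log2 ratio of -0.58 for Srsf4 to 0.41 for Srsf6. Throughout, the log2 ratio is log2((SRSF2-KO + 1)/(WT + 1)) of FPKM, so values above 0 stand for a higher level in the library labelled SRSF2-KO, and differences of low genes are understated.

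Among 11428 rows with at least 1 FPKM in at least 1 library, 627 were at least 2-fold higher and 368 at least 2-fold lower in the library labelled SRSF2-KO. Of these 995 rows, 63% were on the higher side. That share was 54.9% among rows with at least 5 FPKM in at least 1 library. It also depended on scaling. With equal sums outside the 50 most abundant rows it was 80.8% (953 higher, 226 lower). With both libraries rescaled to the same total over all rows (TPM) it was 84.3% (1222 higher, 227 lower). These rescalings moved the KO values by 0.29 and 0.35 log2 units against the WT values. The TPM rescaling also raised the values of both libraries, so the pseudocount of 1 weighed less and ratios of low genes widened. All 36 list medians below lay higher under both rescalings, by 0.18 to 0.29 and by 0.21 to 0.53. Medians below 0 shrank or changed sign and those above 0 grew, and the medians are therefore read against random lists from the same libraries. Among 8944 protein-coding genes with at least 1 FPKM in both libraries, without the Mup, Serpina1 and immunoglobulin families, the counts were 241 higher and 241 lower, a subset chosen after the values were seen.

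The highest log2 ratios belonged to Serpina1b, Serpina1d and Serpina1c, genes of alpha-1-antitrypsin, a protease inhibitor secreted by hepatocytes. They stood at 2257, 963 and 861 FPKM in the library labelled SRSF2-KO and were listed at 0 in the library labelled WT. Their paralogs Serpina1a (437 against 760 FPKM) and Serpina1e (1559 against 2512 FPKM) were present in both. Reads of such near-identical copies are hard to assign, so values of single members are uncertain. Ly6d, a surface protein gene, followed with 112 FPKM against 0.577 FPKM, a 195-fold difference with a counting interval of 93.9 to 559. Cib3, a calcium-binding protein gene, stood at 99.6 against 3.82 FPKM, and Tff3, which codes for a secreted mucosal repair peptide, at 78.8 against 3.63 FPKM.

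Mup18, a major urinary protein gene and another member of a family of near-identical copies, had the lowest ratio, with 2.87 FPKM in the library labelled SRSF2-KO against 875 FPKM in the library labelled WT. Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, stood at 4.63 against 107 FPKM. Of the 24 genes at the extremes, 13 were small nucleolar RNAs or a 5S ribosomal RNA copy listed at 0 in 1 of the libraries. On the higher side these were n-R5s202 (70.6 FPKM), SNORA70 (41.0), SNORA17 (36.3), SNORA25 (31.6) and SNORA14 (18.5), and on the lower side Snord13 (215), Snora31 (35.8), SNORA48 (35.7), Snora68 (28.5), Snora64 (26.4), SNORA8 (26.2), Snora21 (23.2) and SNORA74 (20.7). Another 3 were the unnamed models AC122463.1 (36.8 FPKM against 0), AC132380.1 (0 against 45.7) and AL732626.1 (0 against 44.9). A further row named SNORA17 stood at 26.6 FPKM in the library labelled WT and 0 in the other. Transcripts this short reach high FPKM from very few reads, and no fold was computed against 0.

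**Figure D1:**
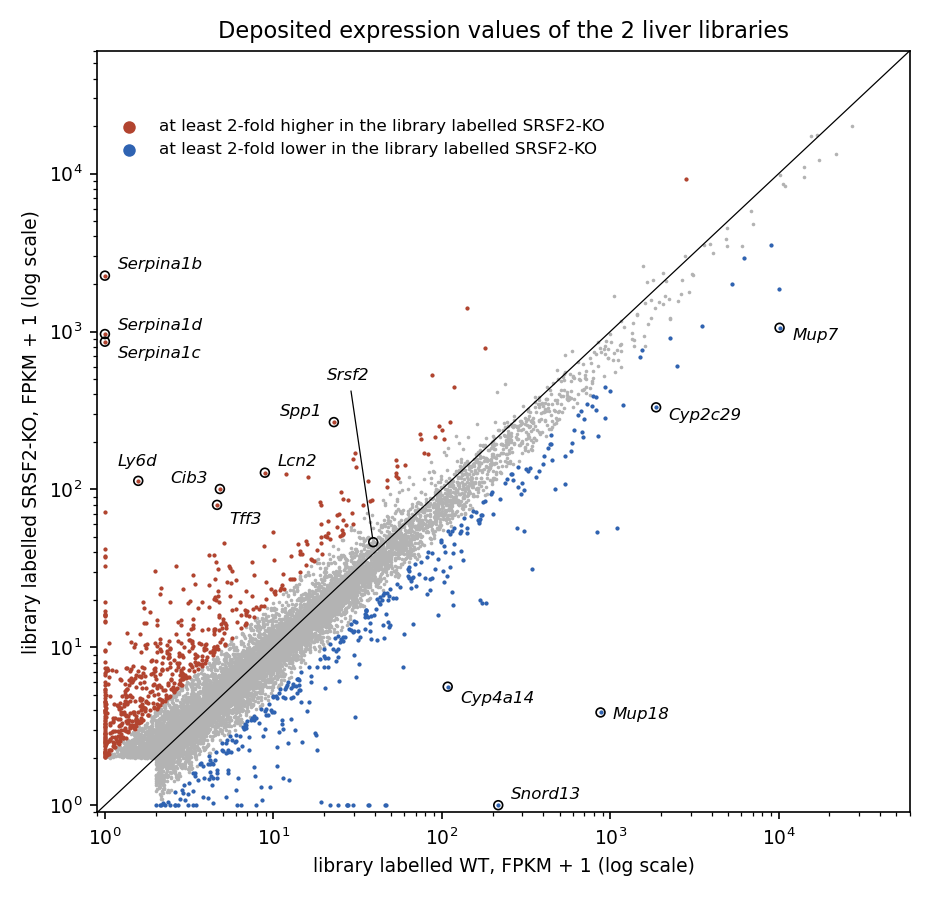
FPKM + 1 of 11428 rows in the library labelled WT (horizontal, log scale) and in the library labelled SRSF2-KO (vertical, log scale), with the diagonal marking equal levels. The 627 rows at least 2-fold higher are red and the 368 rows at least 2-fold lower are blue, and Srsf2 lies beside the diagonal at 45.3 against 38.2 FPKM.

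Outside these families, the protein-coding genes with at least 1 FPKM in both libraries, again a set chosen after the values were seen, were led by Cib3, Tff3 and Lcn2. Lcn2, an iron-sequestering acute phase protein, stood at 127 against 7.91 FPKM. Spp1 (osteopontin, a secreted matrix protein) was at 266 against 21.9 FPKM, 12.2-fold higher in the library labelled SRSF2-KO with a counting interval of 11.1 to 13.3. Ubd, a ubiquitin-like modifier induced by cytokines, was at 22.8 against 1.14 FPKM, and Gpx3, an extracellular glutathione peroxidase, at 27.8 against 2.33 FPKM. Between them ranked the mitochondrial gene mt-Co2, at 44.7 against 4.07 FPKM. Its values were far below those of mt-Cytb (20031 against 27197 FPKM), a gap whose cause was not tested. The lowest ratios after Cyp4a14 were those of the cytochrome P450 genes Cyp2c37 (18.1 against 181 FPKM), Cyp4a10 (17.99 against 172) and Cyp2b10 (2.64 against 29.4). Mfsd2a, a lysolipid transporter, followed with 6.51 against 57.7 FPKM, and Rgs16, a regulator of G protein signalling, with 17.5 against 115 FPKM.

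Genes of hepatocyte metabolism were lower in the library labelled SRSF2-KO in several lists fixed before the data were examined. All 14 measured drug-metabolising cytochrome P450 genes had log2 ratios below 0, and 9 were at least 2-fold lower. The list median was -1.50, at percentile 0 among 10000 random lists matched on expression. Cyp2c37 (-3.25) and Cyp2b10 (-3.06) were lowest, and Cyp2e1, an abundant pericentral enzyme, stood at 1987 against 5250 FPKM. Genes of fatty acid oxidation and PPAR alpha targets had a median of -0.84 (percentile 0), with 15 of 18 members below 0. Cyp4a14 and Cyp4a10 led this side, while Pdk4, the kinase that switches off pyruvate dehydrogenase, was at 7.58 against 1.38 FPKM. In the same libraries the stellate cell and matrix genes had a median of 1.07 and the sinusoidal endothelial markers a median of -0.81, so markers of other cell types differed alongside these groups.

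All 14 genes of the urea cycle and amino acid breakdown lay below 0, with a median of -0.72 (percentile 0.390). Asl, the argininosuccinate lyase, stood at 109 against 299 FPKM, and Tdo2, which starts tryptophan breakdown, at 417 against 1001 FPKM. Of 12 genes of glucose and glycogen metabolism, 11 lay below 0, with a median of -0.61 (percentile 0.720). This median was -0.33 and -0.28 under those rescalings. G6pc and Pck1, key enzymes of gluconeogenesis, were at 34.7 against 133 FPKM and 280 against 927 FPKM. Periportal genes had a median of -0.94 (percentile 0.0100), with Pck1 and Asl lowest, although 5 of the 13 also belong to other lists, and the epithelial adhesion gene Cdh1 was at 31.5 against 4.43 FPKM. The pericentral list had a median of -0.46 and stood within the random lists (percentile 5.40), but below them at 5 FPKM (-0.71 over 9 genes, percentile 1.97) and with a pseudocount of 0.1 (-0.55, percentile 2.23). Cyp2e1 (-1.40) and the glutamate transporter gene Slc1a2 (-1.22) were lowest. Liver transcription factors had a median of -0.41 (percentile 1.16): Cebpb stood at 43.8 against 118 FPKM and Ppara, the receptor that drives fatty acid oxidation genes, at 25.2 against 64.4 FPKM, whereas Foxa2 was at 11.3 FPKM in both. This list no longer stood apart from the random lists at 5 FPKM (median -0.33, percentile 6.87) or among members present in both libraries (-0.37, percentile 3.13), and its median was -0.12 and -0.06 under the equal-sum and TPM rescalings.

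Secreted plasma proteins had a median of -0.38, within the random lists (percentile 45.5), or -0.10 and -0.03 under the equal-sum and TPM rescalings. Ttr, the thyroxine carrier, was at 2938 against 6190 FPKM and Serpina1a at 437 against 760 FPKM, but Serpina1b belonged to the same list. Bile acid synthesis genes had a median of -0.56, at the edge of the random lists (percentile 2.59, or 2.46 with a pseudocount of 3), with Slc27a5 (221 against 444 FPKM) and Akr1d1 (36.8 against 72.6 FPKM) lowest. Cyp7a1, the rate-limiting enzyme of the classic pathway, was the only member of this list above 0, with 36.4 against 23.9 FPKM. Bile acid and sterol transport genes went both ways around a median of -0.30 (percentile 16.3), which was 0.04 under the TPM rescaling and -0.52 over 11 genes at 5 FPKM (percentile 3.08). The uptake carriers Slco1a1 (21.3 against 113 FPKM) and Slc10a1 (152 against 452 FPKM) were lower in the library labelled SRSF2-KO, and the basolateral exporter subunit Ostb was higher (6.47 against 0.658 FPKM). Against random lists not matched on expression, the plasma protein (percentile 0.08), bile acid synthesis (0.04) and transport (1.69) lists stood below, as did the pericentral (0.16) and lipid droplet (1.58) lists.

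Cholesterol synthesis and uptake genes were higher in the library labelled SRSF2-KO. Of 23 members, 18 lay above 0 and 10 were at least 2-fold higher, with a median of 0.83 (percentile 100). Sqle, the squalene epoxidase, stood at 31.0 against 4.50 FPKM and Hmgcs1, an enzyme of the early mevalonate pathway, at 154 against 28.8 FPKM. Fatty acid and triglyceride synthesis genes were mixed, with a median of -0.15 (percentile 90.3) that was 0.13 and 0.19 under the equal-sum and TPM rescalings. Thrsp (145 against 400 FPKM) and Dgat2 (109 against 235 FPKM) were lowest, and Elovl5 and Fasn were highest at log2 ratios of 0.74 and 0.69. The lipid droplet and uptake list had a median of -0.34 (percentile 3.22), or -0.06 and -0.0015 under those rescalings, and stood below the random lists with a pseudocount of 3 (percentile 1.10) and without the filter on low values (percentile 1.85). Fitm1 (10.6 against 31.7 FPKM) and Fabp4 (11.99 against 21.99 FPKM) were lowest, and Lpl, a lipase scarce in adult hepatocytes, was at 29.5 against 4.66 FPKM.

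Genes of the NRF2 and glutathione list were also higher, 15 of 16 above 0 with a median of 0.72 (percentile 100). The glutathione transferase genes Gstm3 (529 against 86.3 FPKM) and Gsta1 (42.7 against 7.78 FPKM) led, whereas Hmox1 and Gclm had log2 ratios of 0.13 and -0.19. Endoplasmic reticulum and integrated stress genes had a median of -0.09 (percentile 70.2), which was 0.19 and 0.25 under the equal-sum and TPM rescalings. Herpud1 (183 against 428 FPKM) and Trib3 (3.14 against 5.32 FPKM) were lowest, and Asns, the asparagine synthetase, stood at 18.5 against 2.77 FPKM. The p53 targets had a median of 0.14 (percentile 91.9), and of 0.24 over 19 genes without the filter, above the random lists (percentile 98.3). Among them were Cdkn1a, the p21 cell cycle inhibitor, at 7.68 against 1.23 FPKM and Plk2 at 7.77 against 2.5 FPKM.

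Cell cycle genes had a median of 0.48 (percentile 99.7), and 21 of 25 lay above 0. Most were expressed at a few FPKM: Cdc20 was at 2.18 against 0.218 FPKM, Ccnd1 (cyclin D1) at 21.7 against 9.29 FPKM and Cdk1 at 4.43 against 1.46 FPKM. Restricting the list to the 5 members with at least 5 FPKM turned its median to -0.13. All 11 measured genes of the fetal liver and liver tumour list lay above 0, with a median of 2.08 (percentile 100). This median was 1.24 with a pseudocount of 3, 0.74 over 18 genes without the filter on low values and 1.46 over the 4 members with at least 1 FPKM in both libraries. Besides Ly6d, the imprinted H19 RNA was at 6.37 against 0.0230 FPKM, Anxa2 at 33.7 against 6.47 FPKM and Afp, the fetal serum protein, at 2.12 against 0.409 FPKM.

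Markers of other liver cell types moved apart. Stellate cell, fibroblast and matrix genes were higher in the library labelled SRSF2-KO, 20 of 22 above 0 and 13 at least 2-fold higher, with a median of 1.07 (percentile 100). Col1a1, the main fibrillar collagen chain, stood at 11.2 against 0.622 FPKM and Lum (lumican) at 23.8 against 3.15 FPKM, while Lrat, a marker of quiescent stellate cells, was at 1.48 against 2.76 FPKM. Bile duct and progenitor markers had a median of 1.29 over 6 genes (percentile 100), or 0.41 over 13 genes without the filter (percentile 99.9). Spp1 and the claudin gene Cldn7 (7.22 against 1.02 FPKM) were highest, and Krt19, a bile duct keratin, was at 0.426 against 1.10 FPKM. Sinusoidal endothelial markers were lower, 14 of 15 below 0, with a median of -0.81 (percentile 0). Oit3 (2.46 against 10.3 FPKM) and the VEGF receptor gene Kdr (2.06 against 7.92 FPKM) were lowest, and the exception was the scavenger receptor gene Stab1, at 19.3 against 8.07 FPKM.

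The macrophage and Kupffer cell list had a median of 0.68 (percentile 100), but its members split, and the 14 present in both libraries with at least 1 FPKM had a median of 0.42. Trem2 (5.22 against 0.387 FPKM), Gpnmb (3.38 against 0.0140 FPKM) and the endotoxin receptor gene Cd14 (8.25 against 1.35 FPKM) were higher in the library labelled SRSF2-KO. Timd4 (0.540 against 3.27 FPKM), Cd5l (18.9 against 43.0 FPKM) and Clec4f (18.3 against 41.5 FPKM), genes typical of resident Kupffer cells, were lower. All 6 measured lymphocyte markers lay above 0, with a median of 0.86 (percentile 99.6), led by Ltb (2.72 against 0.340 FPKM) and Cd52 (54.0 against 27.8 FPKM). The 3 measured neutrophil markers had a median of 1.28 (percentile 99.6), with S100a8 at 8.46 against 1.32 FPKM and S100a9 at 15.9 against 5.97 FPKM. Without a filter on low values these medians were 0.24 and 0.06 and stood within the random lists. Erythroid and blood genes had a median of -0.67 (percentile 0.230), with Alas2 (35.0 against 70.6 FPKM) and Hbb-b2 (5.24 against 10.5 FPKM) lowest. Of the pancreas and adipose genes only Cela1 (5.24 against 13.2 FPKM) and Cfd (0.417 against 1.13 FPKM) were measured.

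Chemokines and cytokines had a median of 1.14 (percentile 100), with 6 of 10 genes at least 2-fold higher, and one of 0.49 over 17 genes without the filter. Cxcl14 stood at 29.2 against 0.972 FPKM and the monocyte attractant Ccl2 at 9.71 against 1.14 FPKM, and Spp1 also belongs to this list. Acute phase genes had a median of -0.20 within the random lists (percentile 60.5), which was 0.05 and 0.11 under the equal-sum and TPM rescalings. Lcn2 and Saa2 (138 against 29.8 FPKM) were highest, and Hamp2 (19.5 against 52.8 FPKM) and Cebpd (5.27 against 13.0 FPKM) were lowest. Interferon-stimulated genes had a median of -0.0035 (percentile 40.4), positive under all 3 rescalings at 0.04, 0.18 and 0.25. Ifit3 (2.97 against 5.85 FPKM) and Gbp2 (1.78 against 2.75 FPKM) were lowest, and Oasl1 was highest at 13.5 against 5.12 FPKM.

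Circadian clock genes had a median of -0.58 (percentile 0.0100). Hlf (10.3 against 24.3 FPKM) and Per1 (4.12 against 9.80 FPKM) were lowest, and Dbp was at 39.4 against 64.9 FPKM. The highest were Arntl, which is expressed in the opposite phase to Dbp, at 1.32 against 0.323 FPKM, and Nr1d1, which peaks near Dbp, at 62.9 against 47.1 FPKM. Clock followed at 4.45 against 3.48 FPKM, while Cry1 and Nfil3 had log2 ratios of -0.65 and -0.38. Female-biased liver genes had a median of -0.73 over 10 genes (percentile 0), with Cyp4a14 and Cyp2b9 (0.0490 against 18.3 FPKM) lowest and Ntrk2, a neurotrophin receptor gene, at 18.3 against 0.679 FPKM. The size of this median depended on the filter: it was -0.12 over 19 genes without one (percentile 0.355) and -2.18 over 6 genes at 5 FPKM. Male-biased genes went both ways, from Mup7 (1055 against 10122 FPKM) and Slco1a1 to Mup20 (9181 against 2815 FPKM) and Selenbp2 (225 against 73.5 FPKM). Their median of -0.01 stood above the matched random lists (percentile 99.1) and was positive under all 3 rescalings, at 0.06, 0.27 and 0.33. It stood within the random lists when these were not matched on expression (percentile 59.2), at 5 FPKM (-0.30, percentile 52.7) and among members present in both libraries (-0.30, percentile 48.9). Y-linked genes were expressed in both libraries, with Eif2s3y at 19.2 against 22.5 FPKM and Ddx3y at 9.21 against 10.6 FPKM, and the median of the sex chromosome genes was -0.17 (percentile 23.1), or 0.08 and 0.14 under the equal-sum and TPM rescalings.

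Among genes of the RNA-processing machinery, SR proteins had a median of 0.22 (percentile 99.7) and no member was 2-fold apart. Srsf6 (21.6 against 16.02 FPKM) and Srsf5 (56.4 against 42.6 FPKM) were highest. Other splicing factors had a median of 0.05 (percentile 99.0), with Son (26.8 against 18.95 FPKM) and Khdrbs1 (9.91 against 6.97 FPKM) highest and again no member 2-fold apart. Ribosomal protein genes had a median of -0.09, above the matched random lists (percentile 99.6), and of 0.19 and 0.26 under the equal-sum and TPM rescalings, with Rps3 (-0.39) and Rplp1 (-0.32) lowest. Against random lists not matched on expression, none of these groups stood apart: the percentiles were 96.1 for SR proteins, 80.1 for other splicing factors and 32.8 for ribosomal proteins. The housekeeping list had a median of -0.12 (percentile 86.6), or 0.15 and 0.21 under those rescalings, with Tfrc (4.12 against 12.9 FPKM) and Pgk1 (83.3 against 123 FPKM) lowest and Actb highest at 415 against 211 FPKM. The 5 most abundant rows were the same genes in both libraries: mt-Cytb (20031 against 27197 FPKM), mt-Nd1 (17584 against 16961), mt-Nd2 (17392 against 15484), Apoa2 (13384 against 21955) and Apoe (12182 against 17320). The 10 highest rows held 24.6% of the summed FPKM in the library labelled SRSF2-KO and 23.8% in the library labelled WT.

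**Figure D2:**
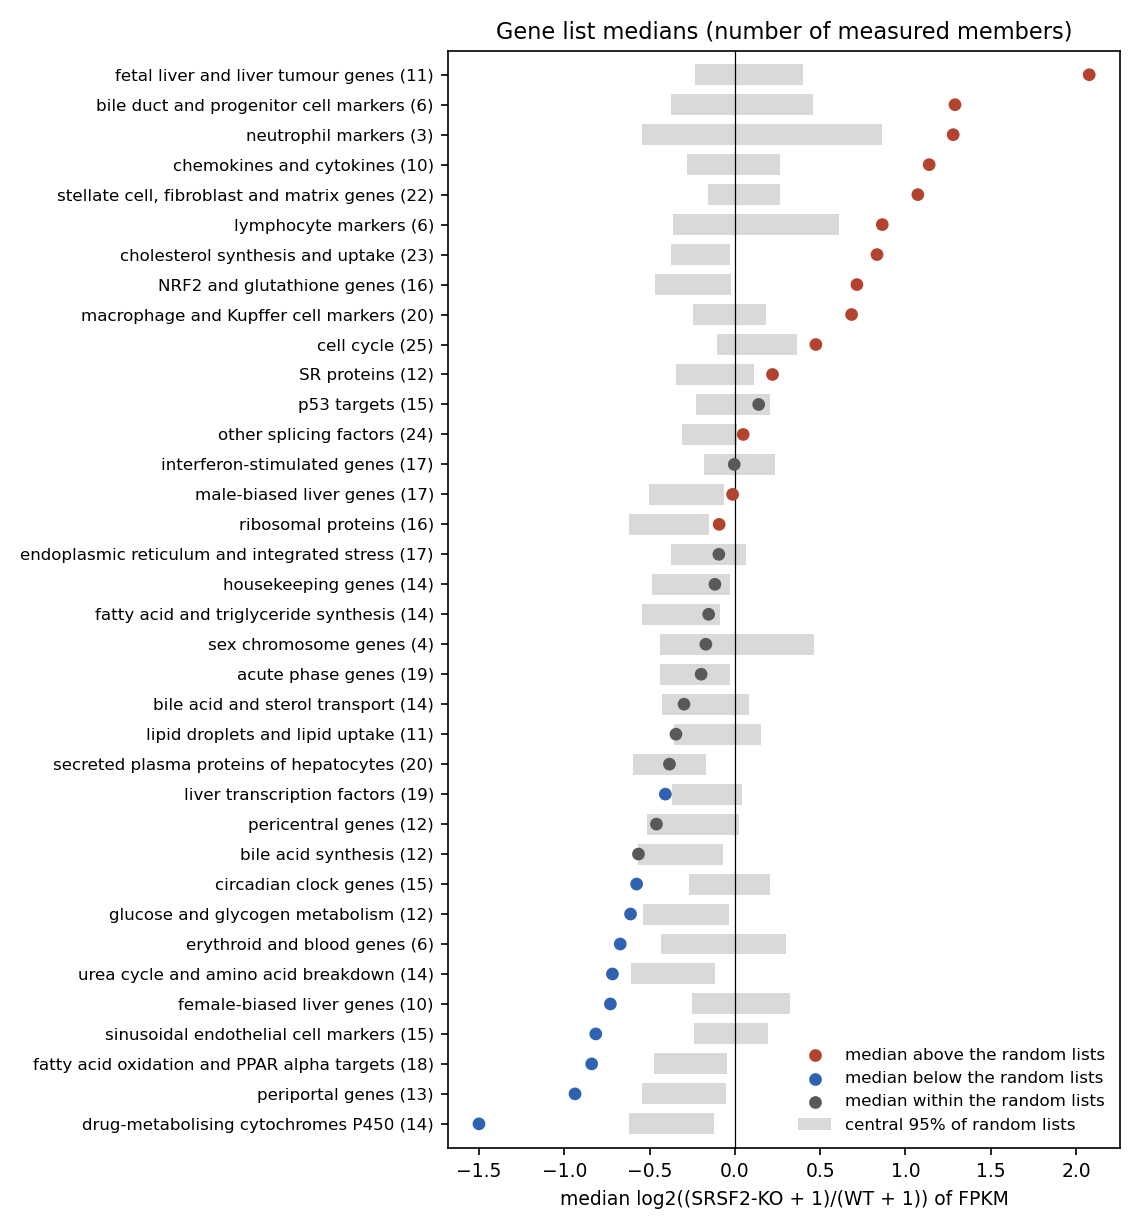
Median log2 ratio of 36 gene lists (points, number of measured members in parentheses) with the central 95% of 10000 random lists matched on expression (grey bars), on a log2 axis. Of the 36 medians, 14 lie above and 10 below the random lists, from -1.50 for the cytochromes P450 to 2.08 for the fetal liver and liver tumour genes.

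**Figure D3:**
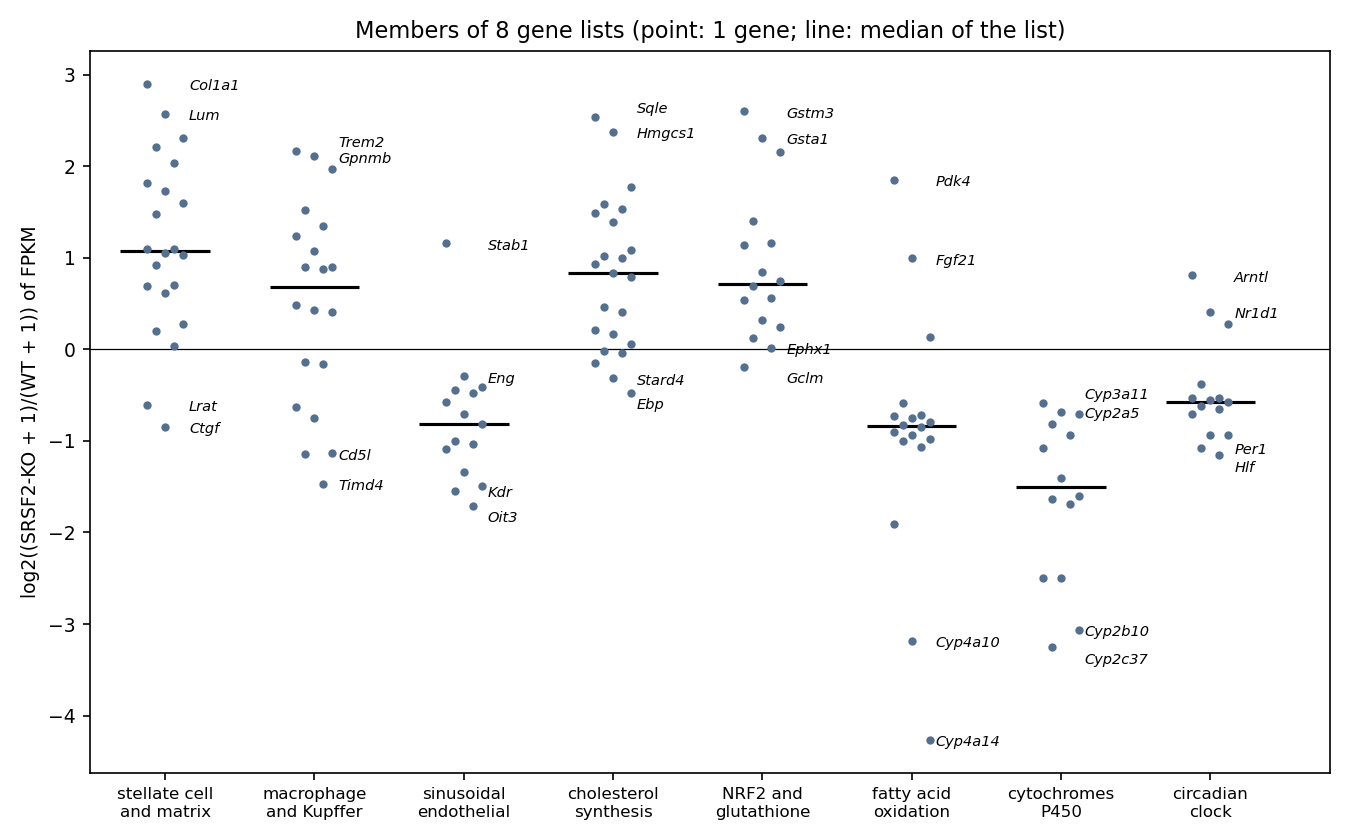
Log2 ratio of each measured member of 8 gene lists (points, vertical log2 axis) with the list median (line) and the 2 highest and 2 lowest genes named. All cytochrome P450 genes lie below 0 around a median of -1.50, whereas the macrophage list spans Trem2 at 2.16 to Timd4 at -1.47.

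Of the 36 lists with at least 3 measured members, 14 medians lay above and 10 below the central 95% of their random lists. For lists of unrelated genes, about 1.80 would lie outside by chance at the nominal 5%, or 2.52 at the 7% found for simulated unchanged lists. Genes of a list can vary together and some lists share members, so neither number is an expectation for these lists. The percentiles describe these 2 libraries and not the genotypes, since 1 library stood for each.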

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

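The protein-coding subset and the restriction of lists to members with at least 1 FPKM in both libraries were chosen after the values were seen, and the other alternatives before. The count of genes at least 2-fold higher in the library labelled SRSF2-KO (627) was 1059 with a pseudocount of 0.1, 314 with a pseudocount of 3, 366 at 5 FPKM, 953 with equal sums without the 50 highest rows, 1222 with the TPM scaling (both libraries to the same total), 160 at 4-fold and 241 in the protein-coding subset. The count of lower genes (368) was 551 with a pseudocount of 0.1, 242 with a pseudocount of 3, 226 with equal sums, 227 with the TPM scaling, 60 at 4-fold and 241 in the subset. The 4-fold threshold, the 5 FPKM filter and the subset count fewer genes by construction. A larger pseudocount shrinks every ratio and a smaller one widens it, and the rescalings raise the KO values against the WT values. These counts therefore moved by arithmetic. With a counting interval that excludes equal levels, 451 higher and 314 lower genes were counted, mostly because 174 higher and 54 lower ones had no read estimate (short or unmatched transcripts): the interval included equal levels for 2 and 0. The median of all 11428 rows, -0.04 as deposited, was 0.20 with equal sums and 0.27 with the TPM scaling. Srsf2 kept a log2 ratio above 0 under every pseudocount and rescaling run.

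Of 36 list medians, those of 3 changed sign after standing apart. Cell cycle genes were at -0.13 at 5 FPKM, where 5 of 25 members were left. Male-biased genes were at 0.061 after centring, 0.27 with equal sums and 0.33 with the TPM scaling. Ribosomal proteins were at 0.19 and 0.26 with the last pair of scalings, which raised every list median, by 0.18 to 0.29 and by 0.21 to 0.53. Some lists no longer stood apart. Against unmatched random lists these were SR proteins (0.22), other splicing factors (0.049), male-biased genes (-0.013) and ribosomal proteins (-0.092). At 5 FPKM these were liver transcription factors (-0.33) and male-biased genes (-0.30), and among members present in both libraries the same lists at -0.37 and -0.30. Without a filter these were lymphocyte (0.24) and neutrophil markers (0.063), over 19 and 10 genes in place of 6 and 3. Others stood apart only under an alternative. Against unmatched lists these were plasma proteins (-0.38), bile acid synthesis (-0.56), bile acid transport (-0.30), lipid droplets (-0.34) and pericentral genes (-0.46). With a pseudocount of 3 these were bile acid synthesis (-0.56) and lipid droplets (-0.34), with 0.1 pericentral genes (-0.55), at 5 FPKM pericentral genes (-0.71), and without a filter lipid droplets (-0.31) and p53 targets (0.24). The cause was not tested except where the member count is given. Of the other 345 values of counts, list medians and Srsf2, 15 list medians changed sign while staying within their random lists, and the rest kept their sign and side, or for counts stayed within 1.5 times. Of 966 values of 161 single genes, 896 kept their side of 2-fold, 37 dropped under it and 33 passed it. The 50 highest rows held 44.1% of the summed FPKM in the library labelled SRSF2-KO and 45.9% in the library labelled WT. In the simulation 89% of 200 4-fold differences came out at least 2-fold apart, and 90% without counting error: of 22 missed, 5 were missed only with it, so most misses came from the pseudocount of 1, not from depth. A share of the extreme ratios rests on short RNAs listed at 0 in 1 library.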

Other observations

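All gene families and tests in this part were chosen after the values were seen, except the gene lists fixed beforehand. Most immunoglobulin genes and all 6 measured MHC class II genes were higher in the library labelled SRSF2-KO. Of 58 immunoglobulin genes, 51 lay above 0 and 38 were at least 2-fold higher, with a median log2 ratio of 1.57 (percentile 100 of matched random lists). This family was not restricted to members present in both libraries or to those with a read estimate. Igkc, the kappa constant region, stood at 781 against 180 FPKM and Ighg1, an IgG heavy chain, at 125 against 10.8 FPKM. MHC class II genes had a median of 1.20, with Cd74 at 213 against 89.8 FPKM and H2-Ab1 at 114 against 46.6 FPKM. MHC class I genes went both ways, 9 of 18 above 0 and 9 below, with 3 at least 2-fold higher and a median of -0.02 (0.04, 0.23 and 0.29 under the 3 rescalings). Matrix metalloproteinase genes had a median of 1.497 over 7 genes, led by Mmp12, the macrophage elastase, at 6.05 against 0.166 FPKM. Collagens had a median of 0.74 over 18 genes, 15 above 0 and 3 below, but their summed FPKM was close, at 233.9 against 213.8. Annexins and S100 proteins had a median of 0.52 over 18 genes, with Anxa5 at 169 against 29.7 FPKM and S100a11 at 119 against 15.1 FPKM. Claudins had a median of 0.46 over 8 genes. Glutathione peroxidases split, 4 of 7 above 0 and 3 below around a median of 1.10, and their summed FPKM was lower in the library labelled SRSF2-KO (1627 against 1947), with Gpx4 at 315 against 497 FPKM. Among macrophage genes outside the fixed list, the chemokine receptor gene Cx3cr1 was at 5.32 against 0.235 FPKM and the scavenger receptor gene Cd163 at 0.12 against 4.27 FPKM.

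Major urinary protein genes were mostly lower, 15 of 20 at least 2-fold lower with a median of -1.55, and their summed FPKM was 15775 against 35038, while Mup20 was higher in the library labelled SRSF2-KO. Carboxylesterase genes had a median of -0.77 over 12 genes (-0.42 with the TPM scaling), with Ces1d at 216 against 851 FPKM. Of 79 nuclear-encoded respiratory chain subunits, 76 lay below 0 by small amounts. Their median of -0.43 stood at the edge within the random lists (percentile 2.56). It was -0.15 and -0.09 with the equal-sum and TPM scalings. Mitochondrial ribosomal proteins had a median of -0.31, below the random lists (percentile 0.16), and of 0.03 with the TPM scaling. Proteasome subunits had a median of -0.26, within the random lists (percentile 26.99), and of 0.02 and 0.08 with the equal-sum and TPM scalings. The nuclear RNAs Malat1 (143 against 59.7 FPKM) and Neat1 (36.8 against 11.7 FPKM) were higher in the library labelled SRSF2-KO.

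Srsf2 was not lower in the library labelled SRSF2-KO. An exchange of the labels, with at most 0.5 of the RNA left in the knockout, would need a WT to KO ratio of 0.5 or less. The ratio was 0.842 with a counting interval of 0.778 to 0.910. Under the same premise the labels as given would need a KO to WT ratio of 0.5 or less, and that ratio was 1.19. The premise thus failed for either labelling, and these values cannot decide between them. Reads from a part of the gene that was not deleted stay open, since the KO to WT ratio of 1.19 is a value for the whole gene and transcript stability is unknown. Hepatocytes that kept Srsf2 stay open as well: its log2 ratio of 0.24 lies near the median of the other SR protein genes (0.20, range -0.58 to 0.41), which a mixture with few deleted cells could also give. These explanations cannot be told apart with 1 value per gene, and an exchange of labels without loss of Srsf2 RNA was not tested.

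Serpina1b, Serpina1c and Serpina1d were listed at 0 in the library labelled WT, and no protein-coding gene outside this family (by GENCODE M21 symbol) had 0 in 1 library and at least 10 FPKM in the other. Reads moved between the copies would keep the family sum, but the summed values of the 5 members (6077 against 3271 FPKM) had a log2 ratio of 0.89, outside the range of 18 other plasma protein genes (-1.07 to 0.10). Moved reads alone would thus need a family sum that differed unlike these genes. Moved reads together with another difference of the family stay open, since the sum cannot separate them. Lost values of the 3 members stay open: the members present in both libraries had a mean log2 ratio of -0.74, inside that range, but a strain or genotype difference confined to the 3 genes would leave the same value. Animals of different strain background may also differ in such families: 7 of 20 Mup genes were at least 4-fold apart, but Mup genes also respond to hormones, 3 of 18 MHC class I genes at least 2-fold apart is a count that matched random lists reach, and both labels name BALB/c, so this stays open. The genotype stays open as an untested explanation.

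List medians of hepatocyte metabolism were lower while those of matrix, macrophage and chemokine genes were higher in the library labelled SRSF2-KO, although 7 of 20 macrophage and 4 of 10 chemokine genes lay below 0. A smaller share of hepatocyte RNA as the whole cause would raise markers of all other cell types alike, but the sinusoidal endothelial markers had a median of -0.81 and an upper quartile of -0.46, below the lower quartile of the matrix genes (0.64). A single scaling factor as the whole cause is argued against by arithmetic, since 1 factor multiplies the FPKM of all genes alike. The medians of the matrix and the cytochrome P450 genes lay 2.57 apart, and the P450 upper quartile (-0.85) lay below the matrix lower quartile (0.64). These lists were picked for this comparison after their medians were seen. An offset that varies with expression is not covered by their distance. A different hour of harvest or feeding could add to the metabolic part: Arntl, Clock, Nfil3 and Cry1 averaged 0.016 and Dbp, Tef, Hlf, Per1 to Per3, Nr1d1 and Nr1d2 averaged -0.65, a difference of 0.66, but Nr1d1 (0.41), Cry1 (-0.65) and Nfil3 (-0.38) went against their sides, and with 1 library per genotype time and genotype cannot be told apart. A change in the cell types that were higher, and the genotype itself, remain open and were not tested.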
